A study of Rattus norvegicus with 18 samples.

How the data were processed

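The data were 18 libraries of rat heart RNA, 6 each from WKY, SHR and QDG-treated SHR. Per the labels' protocols, RNA was extracted with Trizol, rRNA was depleted and libraries were made with a NEB kit for Illumina sequencing. The deposited values are taken as FPKM (fragments scaled to gene length and library size), normalized by the authors. The files do not name the unit: it was inferred from values that are not whole, from sums of 598626 to 676288 that differ between libraries, and from low values that step as whole reads divided by gene length would. A TPM table from which some genes were removed cannot be ruled out. The submitters' processing notes name limma without a version. The aligner, counter, genome build, annotation release and strand setting are not given in the sources used here.

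The files list 37262 genes, none at 0 in every library. The reference of 47357 gene entries used here (assembly GRCr8) held 0 Ensembl identifiers, so 0 identifiers could be matched to a symbol. For that reason 37 gene lists fixed before the data were examined (heart muscle, hypertension, remodelling and cell types of the heart) were not tested. The rule for named genes, also fixed in advance, took for each of SHR against WKY and QDG against SHR the genes with adjusted p under 0.05, groups that do not overlap, a mean of at least 1 FPKM in the higher group and the largest absolute log2 fold changes. It also required a symbol and named members of the lists, which could not be applied. Without symbols 2 identifiers per direction and comparison are printed, 8 in all.

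Absolute depth is unknown. Relative depth was estimated from ratios of low values (genes with a mean under 0.3) between libraries. Within a tolerance of 0.01 on the log2 scale, 13.6% to 15.6% of those ratios stood at an equal read number and 36.2% to 39.7% at ratios of 1 to 4 reads. The estimates spanned a 1.24-fold range. The median SE of a log2 fold change was 0.09.

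Genes with at least 1 FPKM in at least 6 of the 18 libraries were kept (17397: 12396 Ensembl and 5001 NONCODE). Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with an intensity trend and robust empirical Bayes moderation, a mean per group over all 18 libraries and 3 contrasts. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes kept and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values. The design named a count model for count data and limma for FPKM, so limma was used. On simulated data with the real means and spread (17397 genes, 200 changed, 5 runs), the fit recovered 63.8% of 1.5-fold and 85.0% of 2-fold changes for SHR against WKY, with 6.42% of calls false. For QDG against SHR it recovered 63.6% and 84.8%, with 4.63% of calls false.

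Library measures were compared by two-sided exact permutation tests, in Python 3.11.15 with scipy 1.17.1. Comparisons that share libraries were set beside simulated unchanged groups, with each gene drawn independently, and repeated with the shared group split into sets of 3. Alternatives were median centring, quantile normalization, limma without a trend or with sample weights, no filter or a filter at 5 FPKM, pseudocounts of 0.1 and 0.01, the 12 compared libraries alone, a replicate block, a 1.5-fold threshold and each library left out. Added after seeing the data were the removal of genes that switch between 2 levels, a covariate for the balance of abundant genes, and median centring and left-out libraries for the genes of opposite direction. Libraries left out of a comparison they do not belong to were added too.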

Results

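Gene expression was measured by RNA sequencing of rRNA-depleted RNA from rat hearts, in 18 libraries of 3 groups. WKY (Wistar-Kyoto) is the normotensive strain usually set beside SHR, the spontaneously hypertensive rat. The groups were WKY, SHR given NS, and SHR given QDG, with 6 libraries each. The labels do not expand NS or QDG, and do not say whether WKY was also given NS. The strain difference below is therefore SHR given NS against WKY. If WKY was not given NS, an effect of NS cannot be told apart from strain in it. The labels count 6 per group without stating that each library came from a separate animal, so p-values measure the spread between these libraries. The values were read as FPKM and covered 37262 genes, of which 20360 carried Ensembl rat identifiers and 16902 carried identifiers of NONCODE, a catalogue of noncoding transcripts. The files do not pair identifiers with gene names, so genes are given by identifier for a few and by class and count for the rest. Absolute depth is unknown, and the relative depth read from the steps between low values ranged from 0.879 to 1.09 of WKY replicate 1.

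The most abundant gene took 18.7% ± 2.17 of all FPKM in WKY, 13.5% ± 0.833 in SHR and 13.5% ± 0.430 in QDG-treated SHR (SD, n = 6 each). All 6 SHR libraries lay below all 6 WKY libraries (two-sided exact permutation p = 0.00216, the smallest possible, and 0.0162 after Benjamini-Hochberg adjustment over 30 comparisons of library measures). The third most abundant gene moved the other way, from 4.46% ± 0.626 in WKY to 7.37% ± 0.821 in SHR, with 7.46% ± 0.831 in QDG-treated SHR (SD, n = 6 each; exact permutation p = 0.00216 for SHR against WKY, adjusted 0.0162). NONCODE genes together took 7.06% ± 0.286 in WKY and 6.53% ± 0.266 in SHR (SD, n = 6 each; exact permutation p = 0.00649, adjusted 0.0390). None of these 3 shares differed between SHR and QDG-treated SHR beyond the spread between libraries (exact permutation p from 0.190 to 0.874). The second most abundant gene took 8.54% ± 2.04 in WKY, 6.41% ± 0.640 in SHR and 7.76% ± 1.61 in QDG-treated SHR (SD, n = 6 each). For this gene the exact permutation p was 0.0195 for SHR against WKY (adjusted 0.0835) and 0.0952 for QDG-treated SHR against SHR (adjusted 0.317). The fourth most abundant gene took 3.25% ± 1.05 in WKY, 4.68% ± 0.550 in SHR and 3.91% ± 0.517 in QDG-treated SHR (SD, n = 6 each). Its exact permutation p was 0.0152 for SHR against WKY (adjusted 0.0758) and 0.0455 for QDG-treated SHR against SHR (adjusted 0.170). Pairs of libraries correlated at 0.971 to 0.988 on the log2 scale, and no 2 held identical values.

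**Figure D1:**
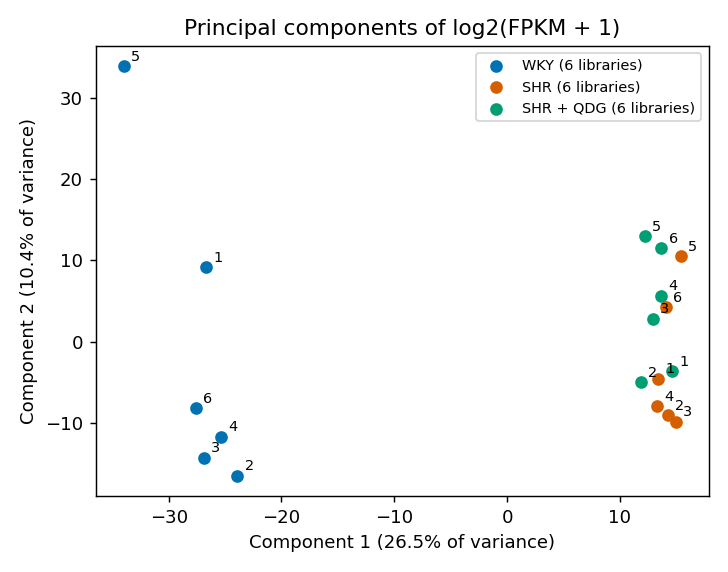
Principal components of log2(FPKM + 1) over the tested genes, with 1 point per library, coloured by group and numbered by replicate. Component 1 (26.5% of the variance) holds the 6 WKY libraries between -34.0 and -23.9 and the 12 libraries of the SHR strain between 11.9 and 15.4, and WKY replicate 5 lies at 33.8 on component 2 (10.4%).

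The first comparison asked which genes differed in the heart between the hypertensive and the normotensive strain. NONRATG027042.1 was at 0.942 ± 0.388 FPKM in WKY and 127 ± 13.8 in SHR (SD, n = 6 each), a log2 fold change of 6.06 (SE 0.13, limma adjusted p = 5.4e-17). ENSRNOG00000003537 lay between 0 and 0.132 FPKM in the WKY libraries and reached 19.3 ± 1.85 in SHR (SD, n = 6), a log2 fold change of 4.25 (SE 0.09, limma adjusted p = 2.2e-17) that became 6.91 and 8.38 with pseudocounts of 0.1 and 0.01. In the other direction, NONRATG011747.2 fell from 11.8 ± 1.17 FPKM in WKY to 0.0602 ± 0.00423 in SHR (SD, n = 6 each), a log2 fold change of -3.59 (SE 0.06, limma adjusted p = 6.7e-19) that became -6.21 and -7.40 with those pseudocounts. The size of both folds depends on the pseudocount, as does that of NONRATG027042.1, which became 7.01 and 7.16 with those pseudocounts. NONRATG026824.1 was present at 9.45 to 23.5 FPKM in all 6 WKY libraries and listed at 0 in all 6 SHR libraries, so no fold is given (limma adjusted p = 1.4e-13). QDG-treated SHR lay on the SHR side for each of these genes, at 108 ± 20.3, 21.5 ± 3.78 and 0.0673 ± 0.0145 FPKM for the first 3 (SD, n = 6), and at 0 in all libraries for the fourth.

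Of 17397 genes tested, 4306 differed between SHR and WKY at an adjusted p under 0.05 (24.8%), 2122 of them higher and 2184 lower in SHR. The more frequent direction depended on scaling, with 2617 higher and 2170 lower after median centring and 2458 higher and 2334 lower after quantile normalization. Most differences were small: the median absolute log2 fold change of the called genes was 0.34, and 240 genes reached 1 or more, 120 in each direction. The 6 values of SHR and of WKY did not overlap for 2135 of the called genes. Over all tested genes that share was 12.5%, against 0.216% by chance.

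Among Ensembl genes 3430 of 12396 (27.7%) were called, 1759 higher and 1671 lower in SHR. Among NONCODE genes 876 of 5001 (17.5%) were called, 363 higher and 513 lower. Ensembl genes were called more often (Fisher's exact test over genes, odds ratio 1.80, p = 7.8e-47), and the direction also differed between the classes (Fisher's exact test p = 2.1e-07). NONCODE calls stayed mostly lower under median centring (436 higher, 501 lower) and under quantile normalization (423 higher, 503 lower). Genes are not independent replicates, and the median SE was larger for NONCODE genes (0.12) than for Ensembl genes (0.08). In the lowest of 5 expression bins lay 2056 of the NONCODE genes and 1424 of the Ensembl genes. In the highest bin 33.8% of NONCODE and 33.9% of Ensembl genes were called. In each lower bin Ensembl genes were called more often, at 21.7% against 12.8% in the lowest and 29.5% against 25.5% in the bin below the highest. The differences within bins were not tested, and Fisher's test over all genes does not separate class from expression.

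A small set of genes was close to present in one strain and absent in the other. Below 0.1 FPKM in all 6 WKY libraries and at 1 or more in all 6 SHR libraries were 7 genes, 5 Ensembl and 2 NONCODE. The reverse held for 4 genes, 2 of each class. All 6 QDG-treated libraries had the SHR pattern in 7 of the 7 and in 4 of the 4. The strand used in counting is not given in the sources used here, so overlapping genes and antisense partners cannot be told apart.

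**Figure D2:**
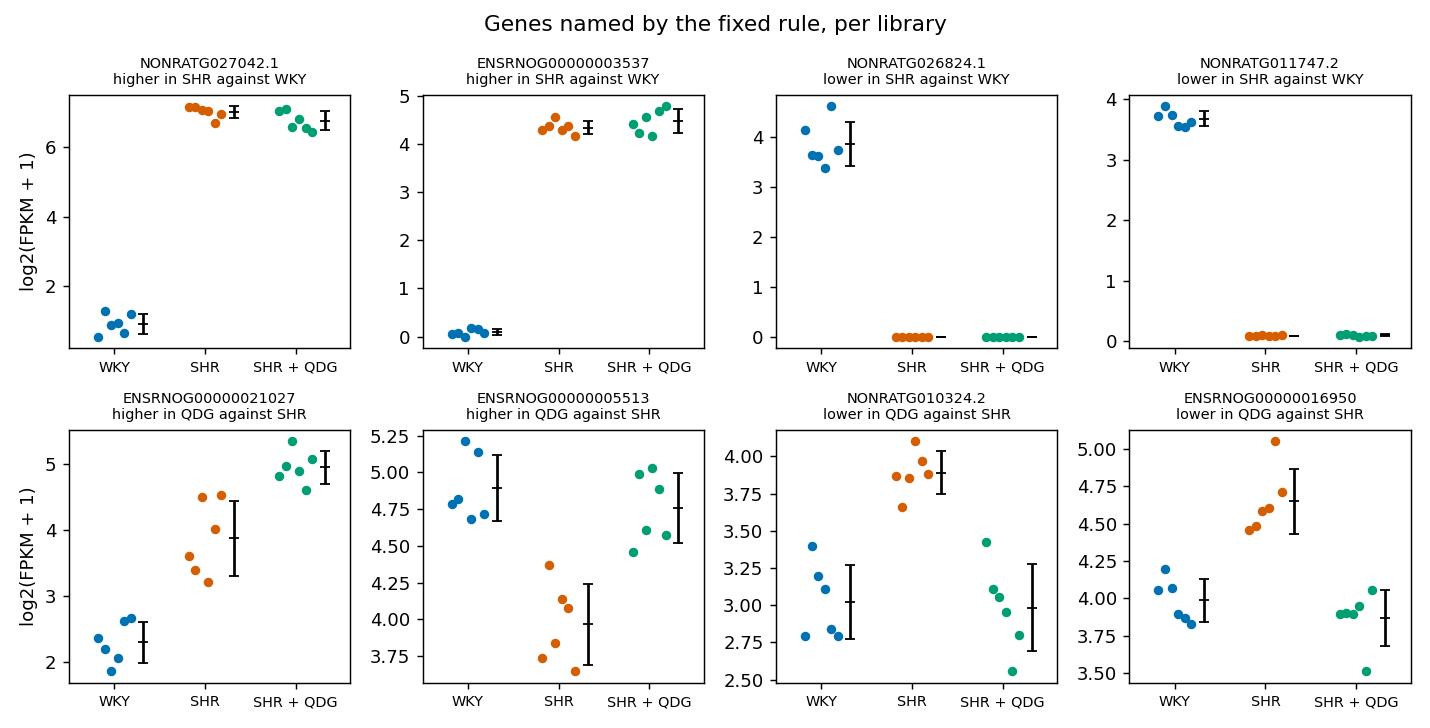
Values of the 8 genes given by identifier, as log2(FPKM + 1) with 1 point per library, and the mean with SD of each group of 6 beside the points. In the upper panels the QDG-treated libraries lie with SHR, and in 3 of the lower panels they lie near WKY, with ENSRNOG00000021027 rising from WKY (3.99 FPKM) through SHR (14.6) to QDG-treated SHR (30.4).

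The second comparison asked what QDG treatment changed in the SHR heart. ENSRNOG00000005513 was at 14.9 ± 3.09 FPKM in SHR and 26.4 ± 4.53 in QDG-treated SHR (SD, n = 6 each), a log2 fold change of 0.79 (SE 0.13, limma adjusted p = 0.0135), with 29.0 ± 4.89 in WKY. NONRATG010324.2 was lower after treatment, at 13.9 ± 1.49 against 7.05 ± 1.64 FPKM (SD, n = 6 each; log2 fold change -0.91, SE 0.13, limma adjusted p = 0.00282), with 7.23 ± 1.47 in WKY. ENSRNOG00000016950 was at 24.4 ± 4.14 in SHR and 13.7 ± 1.76 FPKM after treatment (SD, n = 6 each; log2 fold change -0.78, SE 0.10, limma adjusted p = 0.00136), with 14.9 ± 1.61 in WKY. The largest increase was in ENSRNOG00000021027, from 14.6 ± 6.08 to 30.4 ± 5.64 FPKM (SD, n = 6 each; log2 fold change 1.08, SE 0.22, limma adjusted p = 0.0441). SHR was already above WKY for this gene, at 3.99 ± 1.08 FPKM in WKY (SD, n = 6; log2 fold change 1.58, limma adjusted p = 3.9e-05). Its call after treatment was lost in 20 of 31 alternative settings, with adjusted p from 0.0264 to 0.110.

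In all, 51 genes differed between QDG-treated SHR and SHR (0.293% of those tested), 36 higher and 15 lower. Without QDG replicate 4 the split was 18 higher and 16 lower, and at 1.5-fold or more it was 5 higher and 6 lower. The 51 were 40 Ensembl genes, 30 higher and 10 lower, and 11 NONCODE genes, 6 higher and 5 lower. The NONCODE direction turned to 4 higher and 7 lower after median centring and to 5 higher and 7 lower after quantile normalization. At an unadjusted p under 0.05 there were 1817 of the 17397 genes tested, where a share of about 0.05 would fall there with no effect. Among the 51, the 6 values of the groups did not overlap for 40 (over all tested genes for 200, or 1.15%, against 0.216% by chance), and 2 genes reached an absolute log2 fold change of 1. For 16062 genes (92.3%) the 95% confidence interval of the difference in log2(FPKM + 1) lay within 1.5-fold in either direction, and for 16981 (97.6%) within 2-fold. That scale understates changes of genes with low values, so these shares do not bound the change in FPKM of such genes. Median centring gave 77 genes, 46 higher and 31 lower, quantile normalization 79, sample weights 104, and no filter on low values 30. The count was 30 without SHR replicate 4, 29 without SHR replicate 6, 32 without QDG replicate 2, 31 without QDG replicate 3 and 30 without QDG replicate 6.

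The genes called after treatment mostly ran against the strain difference. Of the 51, 36 were also called between SHR and WKY, and 34 of these had opposite signs: 25 were lower in SHR than in WKY and higher after QDG, and 9 the reverse. These 34 were 27 Ensembl and 7 NONCODE genes. Their median absolute log2 fold change was 0.50 between SHR and WKY, 0.46 between QDG-treated SHR and SHR, and 0.13 between QDG-treated SHR and WKY. The QDG-treated mean lay between those of WKY and SHR for 20 of the 34 and past WKY for 14, and 7 were still called against WKY. Independent lists would share 6.35 genes in opposite directions, and 50 simulations of unchanged QDG libraries against the same SHR libraries gave at most 1, a count limited by their at most 1 call after treatment in either direction.

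Both comparisons use the SHR libraries, which alone gives opposite signs. Opposite signs were found in 46 of the 51 genes (90.2%), and simulated unchanged groups gave 71.8% on average among as many genes of smallest p, reaching 90.2% in 1 of 50 simulations. These simulations drew each gene independently, without shifts shared by many genes of 1 library, so they may spread too little. Across all tested genes the 2 sets of log2 fold changes had a correlation of -0.29 and a covariance of -0.0154, against -0.21 and -0.0112 on average in the simulations. The covariance difference was -0.00428, and the most negative simulated covariance was close to the observed one at -0.0144. With the SHR libraries split into sets of 3, so that none was used in both comparisons, the covariance averaged -0.00502 over 20 assignments (from -0.00659 to -0.00349). These sets gave a median of 12 called genes after treatment (3 to 38) and a median of 8 opposite-direction genes (2 to 24). Summed over the assignments, which share libraries and genes, 242 of 279 calls after treatment (86.7%) were opposite in sign to the strain difference, as were 163 of 183 called in both. The count of 34 fell to 22 without SHR replicate 4, SHR replicate 6, QDG replicate 2 or QDG replicate 4, to 20 without QDG replicate 6, and to 21 with no filter on low values.

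**Figure D3:**
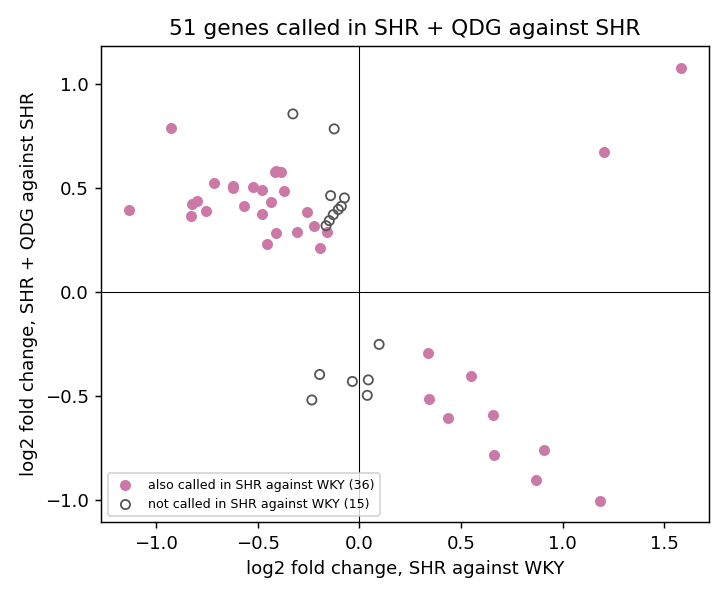
The 51 genes called in QDG-treated SHR against SHR, with the log2 fold change of SHR against WKY on the horizontal axis and that of QDG-treated SHR against SHR on the vertical axis. Filled points are the 36 genes also called between the strains, of which 34 lie in the quadrants of opposite sign and 2 in the quadrant where both are higher.

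The third comparison set treated SHR against WKY. Here 3642 genes differed, 2041 higher and 1601 lower in QDG-treated SHR, comprising 2933 Ensembl and 709 NONCODE genes. Of these, 2841 were also called between SHR and WKY in the same direction and 1 in the opposite direction. Independent lists would share 450 in the same direction, and 20 simulations with no effect in either group gave 0, a count limited by their at most 1 call in either comparison. Both comparisons set the SHR strain against the same WKY libraries, so much sharing was to be foreseen and these values do not test it. The fold changes of the 2 comparisons correlated at 0.87 over genes, against 0.51 simulated with no effect, and at 0.68 with the WKY libraries split into sets of 3. Their covariance was 0.0906, against 0.0116 simulated and 0.0786 with the split libraries. Called against WKY only in treated SHR were 800 genes and only in SHR given NS 1464. In the direct comparison of the SHR groups, 13 of the 800 and 27 of the 1464 were called.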

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

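Chosen after the result was seen were the correlation of WKY replicate 5 with each strain, the share of genes moving the same way in QDG replicate 4, and the relation to the balance of abundant genes. The reading of the depth test of WKY replicate 5 as open was also chosen afterwards, as its first bound counted for depth. The other tests of this part were set before their results. Single libraries stood apart from their group of 6 in 4 of 57 groups of values examined, where chance gives about 1 in 20. The third most abundant gene took 9.01% of FPKM in SHR replicate 4 and 6.86% to 7.34% in the other SHR libraries. QDG replicate 4 listed 6245 genes at 0, against 6520 to 6662 in the others. ENSRNOG00000016950 was at 10.4 FPKM in QDG replicate 5 and at 13.9 to 15.6 in the others.

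WKY replicate 5 was far from the other 5 WKY libraries in 664 of the tested genes, where each of the others was far in 71 to 221. The authors' scaling to library totals is argued against as the cause, since 801 genes were far after quantile normalization (at most 179 in the others), and so is an SHR library under a WKY label, with a mean correlation of 0.980 with WKY and 0.972 with SHR. Lower depth (0.879, the lowest relative depth) stays open: with depth as a covariate 337 genes were far, which met the bound set beforehand only because WKY replicate 1 rose from 221 to 340 in the same fit while the other WKY libraries were at 81 to 106, and in QDG replicate 4, next in depth, 40.4% of the genes moved the same way, within the 28.6% to 75.5% of the other QDG libraries. A further candidate explanation is an extreme of a balance between the second and the fourth most abundant gene, as the share of these genes moving the same way rose with it in QDG (r = 0.983, exact p = 0.00278, adjusted 0.00556; rho = 1, exact p = 0.00278; r = 0.999 without the 2 farthest libraries), but in SHR r was 0.736 (exact p = 0.0931, adjusted 0.0931; rho = 0.600, exact p = 0.242; r = -0.283 without the 2 farthest). As first worded, that test counted the SHR p as evidence against the explanation; the relation did not pass in SHR and its r there rests on 2 libraries, so the explanation stays open without support from SHR, and a difference between animals was not tested.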

How the results depend on the processing

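Each of the 3 counts of changed genes was within 1.5 times its main value in all settings run except those named here. A similar count did not always mean the same genes. For QDG against SHR, the 12 compared libraries alone gave 51 genes, of which 33 were among the main 51. A replicate block kept 33 of the main 51 and the abundant-gene balance as a covariate 31, whereas median centring kept 48 and sample weights 51. For SHR against WKY, the balance covariate gave 4001 genes, 2866 of them among the main 4306. A threshold of at least 1.5-fold left 785 genes for SHR against WKY, 748 for QDG against WKY and 11 for QDG against SHR, which follows from the stricter threshold. For QDG against SHR, 51 genes became 77 with median centring, 79 with quantile normalization, 104 with sample weights and 30 without a filter, and the genes of opposite direction went from 34 to 21 without a filter; the cause was not tested. With SHR sets of 3 libraries their median was 8, with fewer libraries per test. Leaving out 1 library in turn gave 29 to 69 genes for QDG against SHR, 20 to 42 of opposite direction, 3773 to 4368 for SHR against WKY and 3102 to 3703 for QDG against WKY. Median centring shifted QDG replicate 4 by 0.11 on the log2 scale. Of 248 alternative fold changes of the 8 named genes, 0 reversed and 20 lost the call, all in ENSRNOG00000021027, whose log2 fold change ranged from 0.95 to 1.21. Fitted values ranged from 5.76 to 7.16 for NONRATG027042.1, from 4.20 to 8.38 for ENSRNOG00000003537 and from -7.40 to -3.55 for NONRATG011747.2, with the largest sizes at the smallest pseudocount. No fold is read for NONRATG026824.1, listed at 0 in SHR. Little pairing by replicate number was seen: same-numbered libraries correlated at -0.05 to 0.16 (SHR, WKY), -0.06 to 0.13 (QDG, SHR) and -0.04 to 0.19 (QDG, WKY), and 5 of 18 correlated best with their own number. The highest of these correlations was that of replicate 5 in each comparison. Replicate 5 also had the highest balance of abundant genes in each group (3.09 in WKY, 1.02 in SHR and 1.52 in QDG). Whether some factor follows the numbers was not tested. A replicate block gave 4760, 40 and 4028 genes and 25 of opposite direction. The list tests and their alternatives were not run for lack of symbols. Absolute depth is unknown, so what it limits was not measured.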

Other observations

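Chosen after the result was seen were the gap that defines switching genes, the tests of mirrored genes and of switching in both strains, the covariance with SHR libraries split into sets of 3, the balance of abundant genes as a measure, and median centring of the genes of opposite direction; the other tests of this part were set before their results.

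The share of genes that differed between SHR and WKY rose with expression in both classes. Over 5 bins from low to high expression, 21.7%, 22.9%, 25.3%, 29.5% and 33.9% of Ensembl genes were called, and 12.8%, 15.7%, 21.7%, 25.5% and 33.8% of NONCODE genes. The top bin held 296 NONCODE genes, and the differences within bins were not tested. Of the 4306 called genes, 1142 had an absolute log2 fold change under 0.25 and 42 reached 2 or more.

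Other splits of the libraries did not give the called counts. For SHR against WKY 1 of 100 splits drawn from 462, the real one, gave as many as 4306 genes, and the highest other gave 802. For QDG against WKY it was 1 of 100, with 3642 genes and 912 in the highest other, and for QDG against SHR 1 of 100, with 51 and 6. Chance assignment of libraries is argued against for these counts, where 1 of 100 is the smallest share that so many splits can give. In the comparisons with WKY the other splits mix the strains, so low counts there were to be foreseen.

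The 34 genes that differed between the strains and moved the opposite way after QDG were weighed against 4 explanations. Of 100 splits of the SHR and QDG libraries 1, the real one, gave as many and the highest other gave 6, but the other splits called at most 6 genes in all. This argues against chance for the number of calls and says nothing of their direction. The shared SHR libraries alone are argued against: with the SHR libraries split 1 of 100 splits, the real one, had a covariance as negative as -0.00502, although the next was close at -0.00447. The authors' scaling to library totals is argued against as the whole cause, since 50 genes, 32 of the 34 among them, were found after median centring. With the abundant-gene balance as a covariate 30 genes were found, 22 of the 34 among them. Of the 12 lost there 11 lost the call after QDG. The median size of the log2 fold change of the 12 went from 0.40 (median SE 0.08) to 0.36 (median SE 0.08), a smaller change at a similar error. This fit cannot decide on the balance, because WKY replicate 5 weighs heavily on its slope. The balance was 3.09 in that library and 0.584 to 1.84 in the other WKY libraries. The balance therefore stays open as an explanation. With no SHR library shared, 163 of 183 genes called in both comparisons, summed over 20 assignments, were opposite in sign. With the covariance over all tested genes this bears on the direction, found and tested on the same data. Neither was computed with the balance as a covariate. The mean shares of the second and the fourth most abundant gene in QDG-treated SHR lay between those of WKY and SHR. Whether the direction comes from the balance was therefore not tested.

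Some genes stood at 1 of 2 levels in different libraries of the same group, with a gap of more than 2 on the log2 scale: 99 of 37262, of which 75 were NONCODE (gaps of 1 and 3, also looked at, gave 248 and 39 genes). Within both strains 87.9% switched, which the selection for switching within a group favours, so it does not test a strain difference, and depth stays open, although the bound set beforehand (a rho under 0.5 in size or a p of 0.05 or more) counted against it, because 18 libraries cannot separate this rho from 0.5 (rho = -0.274, permutation p = 0.269; r = -0.392, permutation p = 0.106, and -0.130 without the 2 libraries of most extreme depth). Reads moved between gene identifiers may account for part of them: 17 had a gene that mirrored them at a correlation under -0.9, against 1.85 on average and at most 5 with permuted libraries, and 14 of the 17 pairs joined a NONCODE and an Ensembl gene, where 75.8% of switching genes were NONCODE and 47.7% of candidate partners Ensembl, so many pairs would be mixed in any case. In the closest pair the NONCODE gene was at 12.6 ± 0.482 FPKM in 7 libraries and 0.133 ± 0.150 in 11, while its Ensembl partner was at 4.86 ± 0.353 and 10.9 ± 0.663 (SD; r = -0.987). Of the 78 tested, 4 were called between SHR and WKY, and none was among the 51 genes called after QDG or the 8 named.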
